A study of Homo sapiens with 24 samples.

How the data were processed

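RNA from ES8 cells, a human Ewing sarcoma line, and from 1 derivative ES8 line in which SLFN11 was knocked out with CRISPR/Cas9 was measured on Affymetrix whole-transcript expression arrays. Both lines received 0 Gy or 2 Gy of gamma radiation and were harvested 4 h or 24 h later. The 24 arrays fall into 8 groups (line, dose and time) of 3 replicates each. Replicate numbers come from the sample titles, and nothing in the labels says whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

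The deposited values are log2 signals per probe set. Per the submitters' processing notes, the tools were RMA (background correction, quantile normalization and probe set summary) and Affymetrix Expression Console 1.1; which arrays were normalized together is not given in the sources used here. The table holds 24351 probe sets, without missing values. Of these, 17709 have 1 gene symbol in the platform annotation and none has several; 2903 are control probe sets and 3739 others are unnamed here. For 20 genes with more than 1 probe set, the one with the highest mean over all arrays was kept, which left 17687 genes. No filter on dim genes was applied. As arrays carry no read depth, their number limits the precision: the median 95% interval of a difference between 2 groups spanned 0.31 log2 units on either side, and 0.44 for a difference of 2 responses.

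A background level was set per array at the 95th percentile of the negative control probe sets, which lay between 3.46 and 3.81 on the log2 scale. Where a gene was at or below it on every array of a group, the difference is given as "at least N-fold", computed against the higher of the background level and the measured signal, averaged over the arrays of the dim group.

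Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with an intensity trend), with 1 mean per group over all 24 arrays, so that all groups share 1 estimate of the spread. The 12 comparisons are knockout minus parental cells at each dose and time (4), 2 Gy minus 0 Gy in each line at each time (4), 24 h minus 4 h without irradiation in each line (2), and the difference between the 2 lines in the irradiation response at each time (2). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over 17687 genes. Without any difference, a share of about 0.05 of these genes would have an unadjusted p below 0.05. The counts over all genes given below at that level lie under this share, except for time in knockout cells. All adjusted p-values of single genes in the text come from this limma fit unless another fit is named.

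Lists of genes were written before the data were examined: p53 targets, G2/M and mitosis genes, G1/S and DNA replication genes, replication-dependent histone genes, histone genes with polyadenylated transcripts, DNA repair and checkpoint genes, immediate early genes, interferon-stimulated genes, NF-kB and cytokine genes, integrated and unfolded protein stress response genes, EWSR1-FLI1 activated and repressed genes, extracellular matrix and mesenchymal genes, neural genes, cholesterol synthesis genes, hypoxia and glycolysis genes, ribosomal protein genes, mitochondrial respiratory chain genes, markers of epithelial, blood and endothelial cells, and the Schlafen family. Of 699 list entries, 623 were measured. The 21 lists other than the Schlafen family, which is given gene by gene, were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists within a comparison, and again with an estimated correlation. The estimate was 0.32 for replication-dependent histone genes and 0.11 for stress response genes, well above the preset value. For such lists the preset p-values overstate the evidence.

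The genes named were chosen by a rule fixed before the data were examined: SLFN11 and the Schlafen family; up to 10 genes with the largest rise and up to 10 with the largest fall among called genes whose values in the 2 groups did not overlap; up to 4 called members of each list that passed its test, in that direction, or of which at least 5 members were called; and, for irradiation, 14 fixed readouts, of which BTG2 was not measured. Genes named outside this rule are pointed out.

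The fit was tested on simulated data with the real spread and 17687 genes, each drawn independently. Correlated genes and shared deviations of same-numbered replicates were not simulated, so recovery in the real data may differ. For 2 Gy minus 0 Gy in parental cells at 4 h it recovered 25.8% of genes changed by 0.5 log2 units, 92.5% of those changed by 1 and 100% of those changed by 2. For the difference between the responses at 4 h it recovered 6.06%, 64.2% and 98.5%.

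Same-numbered replicates of compared groups deviated together in 4 of the 10 comparisons of 2 groups (every correlation of their deviations from the group means above 0.1): knockout minus parental cells at 0 Gy, 4 h (0.10 to 0.17) and 2 Gy, 24 h (0.15 to 0.23), and 2 Gy minus 0 Gy in the knockout line at 4 h (0.15 to 0.27) and 24 h (0.13 to 0.24). Irradiation in parental cells at 4 h (0.094, 0.21 and 0.41) counts as unpaired under this bound. So does knockout minus parental cells at 2 Gy, 4 h (0.082, 0.16 and 0.33). Different replicate numbers correlated there at up to 0.15 and 0.14. Which comparisons count as paired therefore depends on the bound. Any pairing comes from the values, and the labels do not state a shared culture or day. Alternatives were the replicate number as a block, equal array medians, cyclic loess, a filter on dim genes, all probe sets, no intensity trend, array weights, only the compared arrays, and each array left out. After the data were seen, fits without 2 arrays of narrow signal range, with the interquartile range of each array as a covariate, and with the block on the compared arrays alone were added, as were list tests with an estimated correlation and 1 array left out. Gene order was taken from RefSeq on GRCh38.p14, only to find which genes neighbour each other. Figures were drawn with matplotlib.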

Results

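The series asks how loss of SLFN11, a Schlafen family protein that acts at stressed replication forks, changes the transcriptome of Ewing sarcoma cells and their response to ionising radiation. Parental ES8 cells and 1 SLFN11 knockout derivative were compared on 24 arrays, 3 for each line, dose (0 or 2 Gy) and time (4 or 24 h). Arrays of the same group correlated at 0.985 to 0.993 (Pearson's r across genes, which are not independent replicates) and arrays of different lines at 0.971 to 0.983. The first principal component held 42.2% of the variance and separated the lines. Replicate 2 of the parental 2 Gy groups had the narrowest signal range at both times, with interquartile ranges of 3.28 at 4 h and 3.34 at 24 h, against 3.42 or more on the other arrays.

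SLFN11 was lower in the knockout line on every array. Without irradiation its log2 signal at 4 h was 8.25 ± 0.11 (SD, n = 3) in parental cells and 6.79 ± 0.34 (SD, n = 3) in knockout cells, and at 24 h 8.41 ± 0.11 and 7.04 ± 0.05. After 2 Gy the means were 8.11 ± 0.11 and 6.58 ± 0.21 at 4 h, and 8.42 ± 0.18 and 6.91 ± 0.15 at 24 h. The differences were -1.46, -1.38, -1.53 and -1.51 (SE 0.13 each), with limma adjusted p of at most 1.26e-09. The signal in knockout cells stayed above the background level of 3.46 to 3.81, and a probe set outside the edited part, or an edited but stable transcript, would not show a loss of the protein. SLFN5, SLFN12L, SLFN13 and SLFN14 were not called between the lines. Mean signals in parental and knockout cells were below background for SLFN12L (2.91 and 3.03), SLFN13 (2.44 and 2.34) and SLFN14 (2.54 and 2.68). For these, the absence of a call says nothing about a difference. Over all conditions, SLFN12 also had mean signals below background in parental (3.39) and knockout cells (3.20). It was called lower at 2 Gy, 4 h only (limma adjusted p = 0.029), where it was not above background on any knockout array, so no fold is given. That call was lost without replicate 1 or 3 of the parental arrays or replicate 2 or 3 of the knockout arrays of that condition (adjusted p = 0.060, 0.0997, 0.067 and 0.23).

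**Figure D1:**
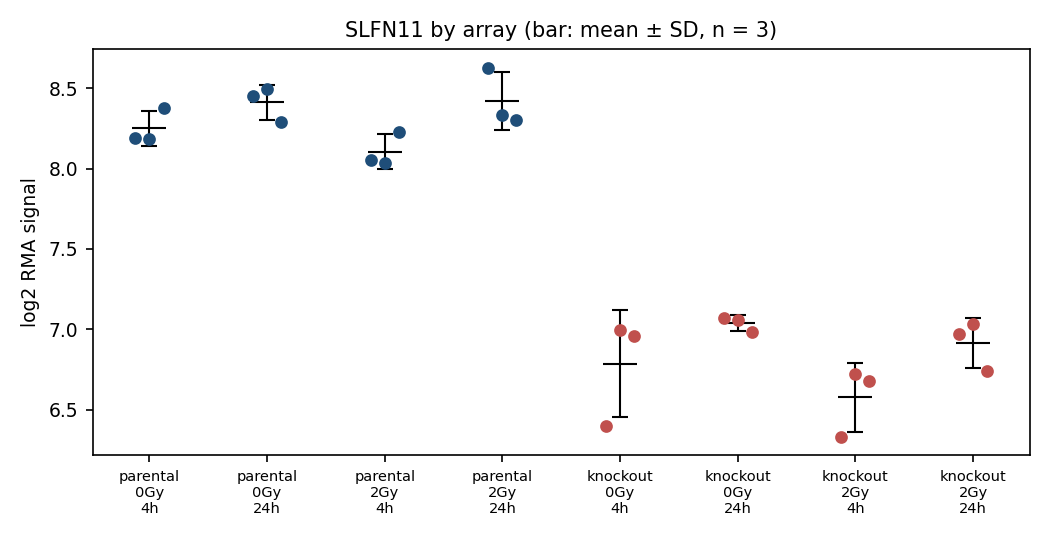
SLFN11 log2 RMA signal on each of the 24 arrays by line, dose and time, with the mean ± SD of each group (n = 3). Parental groups average 8.11 to 8.42 and knockout groups 6.58 to 7.04.

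Between the unirradiated lines at 4 h, the genes with the largest rises in the knockout line were WFDC1 (log2 change 3.40, SE 0.20), FLT1, a VEGF receptor (at least 4.24-fold higher, since it was not above background in parental cells), CMTM7 (2.92, SE 0.12), FAM162B (2.66, SE 0.23), SAMSN1 (at least 4.22-fold higher), TMEM200A (2.51, SE 0.17), the pituitary transcription factor POU1F1 (2.48, SE 0.26), the homeobox gene HHEX (2.35, SE 0.17), the sphingosine-1-phosphate receptor S1PR1 (2.32, SE 0.21) and the neuropeptide gene NTS (2.32, SE 0.22). The largest falls were of SYCP1, which encodes a synaptonemal complex protein (at least 10.8-fold lower), the receptor phosphatase PTPRG (at least 5.76-fold lower), CYTL1 (at least 6.66-fold lower), DCHS2 (-3.18, SE 0.20), the phosphodiesterase PDE1B (-3.02, SE 0.18), the calcium sensor VSNL1 (-2.99, SE 0.19) and SERPINF1 (-2.94, SE 0.15). MBD3L3, MBD3L4 and MBD3L5 fell by 3.98, 4.13 and 3.89, but are near-identical copies that the probe sets may not separate. In all, 1109 genes were higher and 972 lower, of which 203 and 193 by at least 2-fold (limma, adjusted p below 0.05; lowest adjusted p 8.43e-18).

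Lists fixed beforehand split in both directions at 4 h without irradiation. Of 42 extracellular matrix and mesenchymal genes, 11 rose and 7 fell, with higher ACTA2 (1.62, SE 0.13), FBN1 (1.48, SE 0.17) and MMP2 (1.14, SE 0.12) and lower CDH11 (-1.84, SE 0.15). Of 28 genes activated by EWSR1-FLI1, the fusion oncoprotein of Ewing sarcoma, 8 rose, among them PRKCB (1.05, SE 0.15), and 10 fell, among them PPP1R1A (-2.07, SE 0.14). Among 33 immediate early genes, 6 rose, including EGR1 (1.45, SE 0.28) and the ERK phosphatase DUSP6 (1.56, SE 0.20), and 2 fell, including MYC (-1.05, SE 0.11). Of 41 p53 targets, 8 rose and 5 fell, with higher FAS (1.42, SE 0.19), a death receptor, and CCNG1 (0.74, SE 0.08). Of 27 stress response genes, 3 rose and 5 fell, among them the asparagine synthetase ASNS (-0.75, SE 0.13) and the amino acid transporter subunit SLC7A5 (-0.93, SE 0.14). In the replication list of 47, DSCC1 rose by 1.46 (SE 0.10) and the sliding clamp PCNA fell by 0.57 (SE 0.07). These 6 lists did not pass the list test. Mitosis genes (median 0.17, 6 of 46 higher and 1 lower) and cholesterol synthesis genes (median 0.12, 3 of 20 higher, among them SQLE at 0.68) did, and neither held with an estimated correlation (adjusted p = 0.68 for both). Of the mitosis genes called higher, MKI67, CDK1 and KIF11 lie in a stretch of neighbouring genes, WASHC2A to KNDC1, where 343 of 462 were higher. How far that stretch carries the mitosis difference between the lines was not tested. The mitosis median was 0.07, not past the preset test (adjusted p = 0.14), without knockout 0 Gy, 4 h replicate 1 and 0.12 without parental replicate 3. The cholesterol call was lost without knockout replicate 2 (0.06) or 3 (0.09) or parental replicate 1 (0.15), and its median was 0.24 without knockout replicate 1. Markers of epithelial (median -0.15), blood (-0.06) and endothelial cells (0.08) did not pass it (adjusted p = 0.30, 0.47 and 0.32).

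The line difference recurred in the other conditions, which use other arrays. At 0 Gy, 24 h, 1145 genes were higher and 901 lower; at 2 Gy, 4 h, 1215 and 908; at 2 Gy, 24 h, 1112 and 1005. In all 4 comparisons 626 genes were called higher and 502 lower, 139 and 118 of them by at least 2-fold each time. Independent lists would share fewer than 1 gene, but comparisons of the same 2 lines with 1 shared estimate of the spread are not independent. CMTM7 ranged from 2.88 to 3.003, HHEX from 2.35 to 2.49, MYC from -0.98 to -1.26, SLC7A5 from -0.93 to -1.09 and ACTA2 from 1.39 to 1.62. CMTM7, HHEX, FAS, ACTA2, SYCP1, PCNA and PPP1R1A lie among neighbouring genes that shifted the same way, and S1PR1 among genes that shifted the other way. Over genes with a mean signal above 6, these stretches had medians of 0.49 (CMTM7), 0.37 (HHEX, FAS and ACTA2), -0.19 (SYCP1) and -0.24 (PPP1R1A). Each gene in these brackets changed by more, such as SYCP1 (-4.31 to -4.86), while PCNA (-0.40 to -0.60) changed by less than its stretch (-0.72). Replication-dependent histone genes were lower in knockout cells at 0 Gy, 24 h (median -0.23, 10 of 32 called, list test adjusted p 5.14e-05); this list, the mitosis list (0.17) and the respiratory chain list (-0.09) had adjusted p = 0.79 with an estimated correlation. The histone median was -0.13, no longer past the preset test (adjusted p = 0.076), without knockout 0 Gy, 24 h replicate 3, and -0.35 without parental replicate 3; the respiratory chain call was lost without parental replicate 1 (-0.08) or 3 (-0.09) or knockout replicate 3 (-0.09). At 2 Gy, 4 h, mitosis genes were higher (median 0.34, 25 of 46 called; adjusted p = 0.29 with an estimated correlation), and p53 targets (0.11) and stress response genes (-0.09) passed the preset test but not the estimated one (adjusted p = 0.26 and 0.78), the latter also not without parental replicate 3 (-0.07) or knockout replicate 1 (-0.03). At 2 Gy, 24 h, 10 of 27 stress response genes were lower (median -0.16; adjusted p = 0.56 with an estimated correlation), with ASNS at -1.51. Cholesterol synthesis, mitosis, replication and polyadenylated histone genes were also higher there in the preset test (medians 0.18, 0.09, 0.09 and 0.29), with adjusted p of 0.70 or more with an estimated correlation. Without parental 2 Gy, 24 h replicate 2, the array of narrow signal range, the mitosis and replication medians were both 0.04 and not past the preset test, and without parental replicate 1 both were 0.14. These calls were also lost without knockout replicate 3 (0.08 and 0.06), that of mitosis genes without knockout replicate 1 (0.07), that of cholesterol genes without parental replicate 3 (0.13), and that of polyadenylated histone genes without parental replicate 3 (0.24) or knockout replicate 1 (0.28) or 2 (0.25). The knockout line is 1 derivative, so effects of SLFN11 loss and of deriving the line are not separated by these comparisons.

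**Figure D2:**
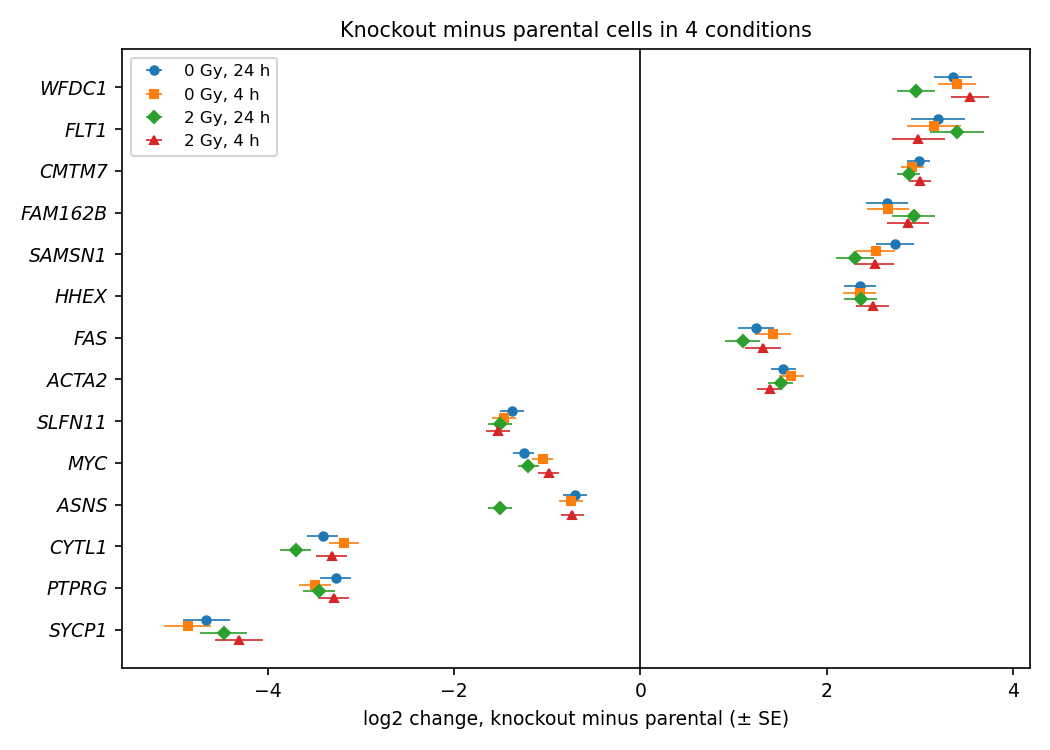
Log2 change between knockout and parental cells (± SE, horizontal axis) of named genes (vertical axis) in 4 conditions, each from 3 arrays per line. SLFN11 lies between -1.38 and -1.53 and CMTM7 between 2.88 and 3.003 in all conditions.

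At 4 h after 2 Gy, mitosis genes fell in parental cells. Among members of the list, the hyaluronan receptor HMMR changed by -0.998 (SE 0.19), the centromere motor CENPE by -0.94 (SE 0.13), KIF20A by -0.89 (SE 0.12), CCNB1 (cyclin B1) by -0.76 (SE 0.10), AURKA (Aurora A kinase) by -0.72 (SE 0.09) and PLK1 (polo-like kinase 1) by -0.57 (SE 0.07). Outside the list, SGO2, which protects sister chromatid cohesion, changed by -1.03 (SE 0.19), DEPDC1 by -0.98 (SE 0.16) and GAS2L3 by -0.97 (SE 0.14). The median of the 46 mitosis genes was -0.50; 22 were called lower over all genes and 40 adjusted over the list alone, none higher. The fixed readouts CDKN1A (-0.00, SE 0.23), MDM2 (-0.23, SE 0.14), GDF15 (0.13, SE 0.22) and FAS (-0.24, SE 0.19) were not called, nor was any of 41 p53 targets. In all, 40 genes were lower and none higher (limma, adjusted p below 0.05). The list test gave an adjusted p of 1.62e-82, and adjusted p = 0.0008 with an estimated correlation; 4 further lists passed the preset test but not the estimated one. With array weights 59 genes were lower and 8 higher. Without replicate 2 of the parental 2 Gy, 4 h group, the array of narrow signal range, 22 genes were called, and SGO2 (-0.93) and HMMR (-0.72) were not.

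In knockout cells at 4 h, the same list had a median of -0.28 and no gene was called over all genes (limma, lowest adjusted p 0.105). At an unadjusted p below 0.05 there were 583 genes, fewer than the share of 0.05 of 17687 genes that would pass without any difference. CCNB1 changed by -0.46 (SE 0.10), CDC20 by -0.38 (SE 0.09) and PLK1 by -0.26 (SE 0.07), none called. Of the 46 mitosis genes 29 were lower adjusted over the list alone (list test adjusted p = 0.0063 with an estimated correlation, and 0.069 with a median of -0.20 without knockout 0 Gy, 4 h replicate 1). Both histone lists passed the preset test alone (medians -0.09 and -0.12; adjusted p = 0.65 and 0.59 with an estimated correlation). Without 1 array their medians ran from -0.05 to -0.15 (call lost for 3 of 6 arrays) and from -0.09 to -0.19 (4 of 6). With the replicate number as a block, 11 genes were called, 10 lower, among them AURKA, CCNB1, CENPE, PSRC1 and PRC1, and 1 higher, KLK6 (named for their blocked calls). Without replicate 3 of the knockout 0 Gy, 4 h group 1 gene was called. CDKN1A changed by -0.16 (SE 0.23) and MDM2 by -0.04 (SE 0.14).

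The 40 genes called in parental cells at 4 h all went the same way in knockout cells, where 32 had an unadjusted p below 0.05, with medians of -0.70 and -0.36. The difference of the responses itself was called for no gene (limma; 461 at an unadjusted p below 0.05, lowest adjusted p 1.00), with PLK1 at 0.31 (SE 0.10) and CCNB1 at 0.29 (SE 0.14). These 40 genes were picked on the parental arrays, which widens their gap. As a list, mitosis genes differed by a median of 0.20, past the preset test (adjusted p 1.70e-11) but not the estimated one (adjusted p = 0.92). The median was 0.11 without parental 2 Gy, 4 h replicate 2, the array of narrow signal range, 0.13 without parental 0 Gy, 4 h replicate 1 or knockout 0 Gy, 4 h replicate 3, and 0.30 without knockout 0 Gy, 4 h replicate 1.

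At 24 h after 2 Gy, 12 genes were higher and none lower in parental cells. They included the transcription factor CREB5 (1.60, SE 0.18), NIBAN1 (1.23, SE 0.23), CHAC1, which degrades glutathione (1.22, SE 0.16), the AP-1 subunit JUN (1.19, SE 0.22), SMAGP (0.88, SE 0.17), ALDH1L2 (0.87, SE 0.16), the cystathionine lyase CTH (0.86, SE 0.17) and the BH3-only gene PMAIP1 (0.79, SE 0.16). Stress response genes rose (median 0.23, 2 of 27 called and 10 adjusted over the list alone), as did immediate early genes (0.12, 1 of 33 called), while replication-dependent histone genes fell (-0.33, none of 32 called and 14 adjusted over the list alone). Each held with an estimated correlation (adjusted p = 0.017, 0.022 and 0.017), unlike 5 further lists that passed the preset test. Mitosis genes had a median of 0.04 and p53 targets of 0.01, neither past the test; CDKN1A changed by 0.24 (SE 0.23) and MDM2 by -0.08 (SE 0.14). The count of 12 rests on single arrays: without parental 0 Gy, 24 h replicates 1, 2 and 3 it was 7, 6 and 3, and without parental 2 Gy, 24 h replicates 1, 2 and 3 it was 3, 4 and 7. Without both arrays of narrow signal range it was 4. Of these 8 named genes, CREB5 and CHAC1 kept their call without each of these 6 arrays. With only the compared arrays 22 genes were higher and 6 lower, and with array weights 17 and 5. In the estimated test, the histone call was lost without parental 0 Gy, 24 h replicate 1 (-0.28) or parental 2 Gy, 24 h replicate 3 (-0.25), and the stress response call without the former (0.25). The immediate early call was lost without parental 0 Gy, 24 h replicate 1 (0.05) or 2 (0.08) or parental 2 Gy, 24 h replicate 1 (0.13) or 2 (0.12), and its median was 0.21 without parental 0 Gy, 24 h replicate 3.

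In knockout cells at 24 h no gene was called (limma; 736 at an unadjusted p below 0.05, lowest adjusted p 0.924). With the replicate number as a block the count was 0 over all arrays and 42 on the compared arrays alone (34 higher and 8 lower), a fit added after the data were seen. CREB5 changed by 0.42, CHAC1 by 0.15 and JUN by -0.18, and ATF3 by 0.78 (SE 0.22). The histone list had a median of 0.00 and the stress response list of -0.02. Immediate early, interferon-stimulated, extracellular matrix and ribosomal protein genes passed the preset test with medians of 0.04 to 0.11, and adjusted p of 0.14 or more with an estimated correlation. Without 1 array these calls were lost for 1, 2, 2 and 3 of the 6 arrays, with medians down to 0.03, 0.04, 0.03 and 0.0066. The difference of the responses was called for no gene (limma; 560 at an unadjusted p below 0.05, lowest adjusted p 0.295), with CREB5 at -1.18, CHAC1 at -1.07 and JUN at -1.37. These genes were picked on the parental arrays, which widens their gap. As lists, histone genes differed by a median of 0.34 and stress response genes by -0.22, both also with an estimated correlation (adjusted p = 0.042). The histone median was 0.22 without knockout 0 Gy, 24 h replicate 3 (adjusted p = 0.21). In this test, also run after the data were seen with each of the 12 arrays left out, the histone call was lost 8 times (medians 0.22 to 0.44) and the stress response call 9 times (-0.18 to -0.27). With the signal range of each array as a covariate, also added later, the medians were 0.34 and -0.23 (adjusted p = 0.064 and 0.057).

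Without irradiation, no gene was called between 24 h and 4 h in parental (limma; 830 at an unadjusted p below 0.05, lowest adjusted p 0.329) or knockout cells (1215, lowest adjusted p 0.391). Cholesterol synthesis genes were higher at 24 h in both lines (medians 0.21 and 0.20) and mitosis genes lower (-0.09 and -0.06) in the preset list test. In parental cells 6 lists and in knockout cells 7 passed that test, none with an estimated correlation (adjusted p of 0.21 or more). The mitosis median was 0.014 in knockout cells without knockout 0 Gy, 4 h replicate 1 and -0.13 without replicate 3, and -0.03 in parental cells without parental 0 Gy, 4 h replicate 1. Without these replicate 1 arrays the preset mitosis call was lost in both lines, and without the knockout one also that of cholesterol synthesis genes in knockout cells (0.11).

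**Figure D3:**
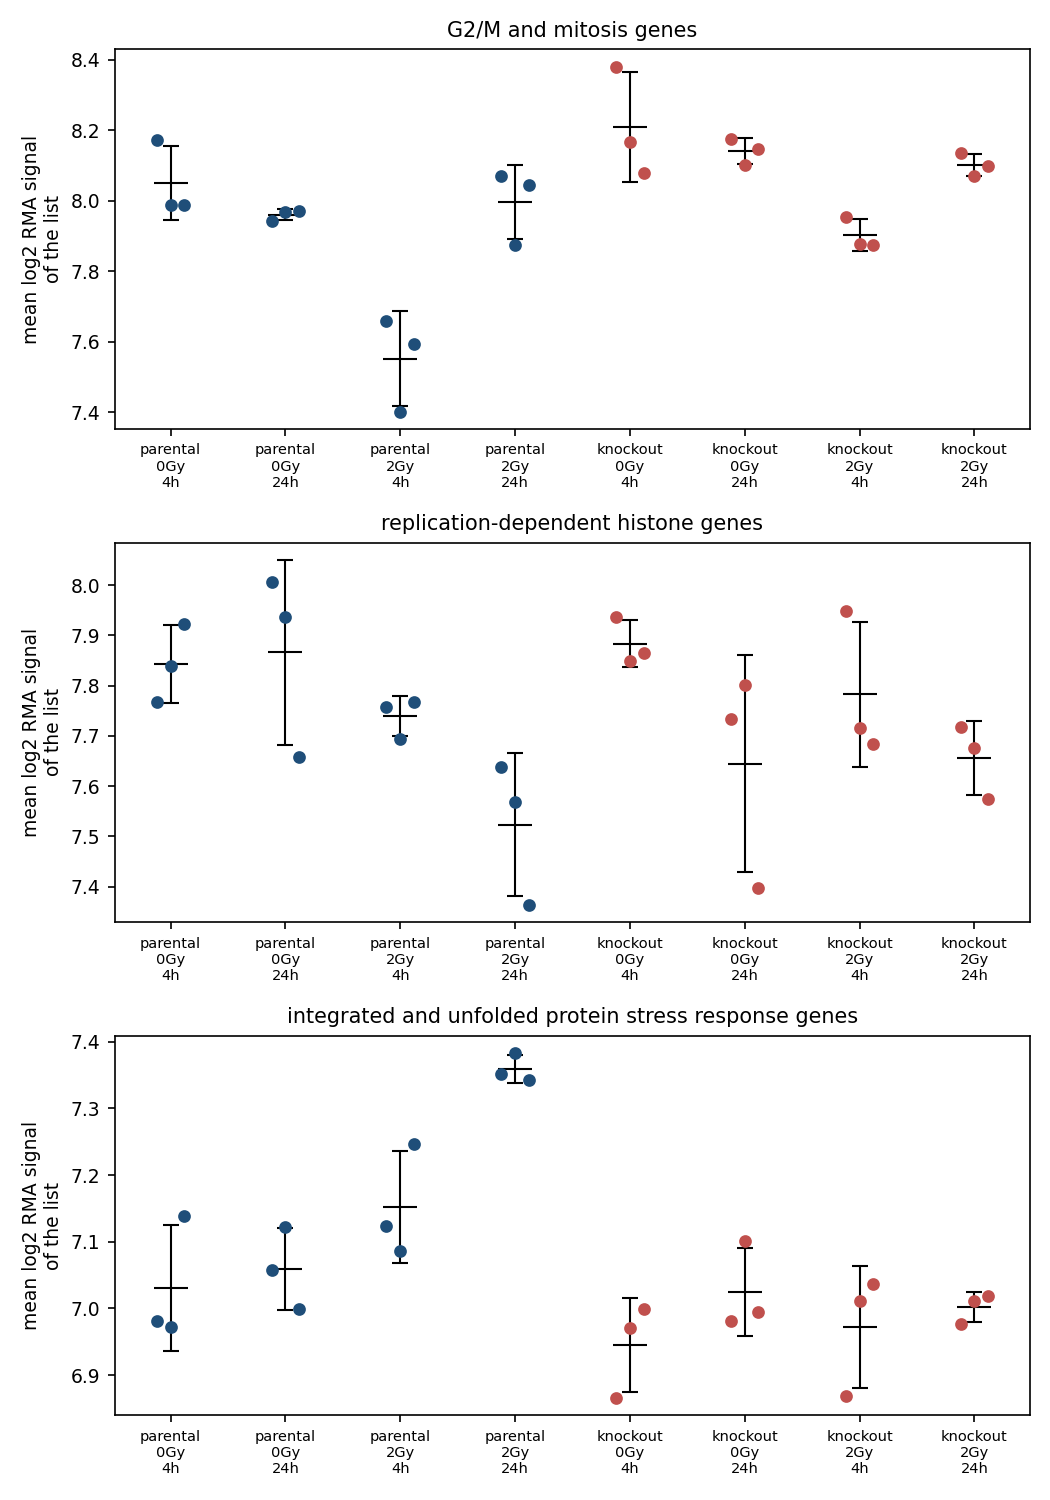
Mean log2 RMA signal of 3 gene lists on each array by line, dose and time, with the mean ± SD of each group (n = 3). The mitosis list averages 7.55 in parental cells 4 h after 2 Gy, and the stress response list 7.36 in parental cells 24 h after 2 Gy.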

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

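The tests of narrow signal range, irradiation, time in culture and gene order, and the list tests with an estimated correlation and 1 array left out, were chosen after the results were seen; the splits of the arrays and the block test on genes near and above background were set before their results.

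A total of 11 differences between the lines in the irradiation response of a gene list passed the preset list test. At 4 h mitosis genes differed by a median of 0.20. At 24 h replication-dependent histone genes differed by 0.34, histone genes with polyadenylated transcripts by 0.34, stress response genes by -0.22, EWSR1-FLI1 repressed genes by 0.15, cholesterol synthesis genes by 0.11, G1/S and DNA replication genes by 0.080, EWSR1-FLI1 activated genes by -0.076, mitochondrial respiratory chain genes by 0.06, mitosis genes by -0.059 and ribosomal protein genes by 0.040 (knockout minus parental response). With an estimated correlation, the replication-dependent histone and stress response genes kept an adjusted p of 0.042 each, and the others did not pass. With each of 12 arrays left out, the preset 24 h call was lost 6 times for EWSR1-FLI1 repressed (0.10 to 0.22) and cholesterol synthesis genes (0.014 to 0.17). It was lost 5 times for mitosis genes (-0.024 to -0.13) and 4 times for EWSR1-FLI1 activated (-0.029 to -0.12) and respiratory chain genes (0.033 to 0.098). Ribosomal protein genes lost it 3 times, replication genes 1 time, and both histone lists and the stress response list 0 times.

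The fall of mitosis genes at 4 h in parental cells had a median of -0.50. Leaving out the array of narrow signal range gave -0.43 (adjusted p = 0.0016 with an estimated correlation), and the signal range as a covariate gave -0.47 (adjusted p = 0.0013), which argues against either as the whole cause. The knockout line, on other arrays, gave -0.28 (adjusted p = 0.0063), as irradiation would, though without knockout 0 Gy, 4 h replicate 1 it gave -0.20 (adjusted p = 0.069). Whether SLFN11 loss weakens the fall stays open, since the difference did not pass with an estimated correlation and fell from 0.20 to 0.11 without the array of narrow signal range.

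For the 24 h lists, leaving out the array of narrow signal range left the histone difference at 0.38 and the stress response difference at -0.24 (adjusted p = 0.043 each with an estimated correlation). Over the 12 arrays left out in turn, the histone call was lost 8 times and the stress response call 9 times, and without knockout 0 Gy, 24 h replicate 3 the histone difference was 0.22 (adjusted p = 0.21). With the signal range as a covariate they were 0.34 and -0.23 (0.34 and -0.22 before), and the adjusted p rose to 0.064 and 0.057, which ended both calls. The SE of the list mean went from 0.151 to 0.153 for histone and from 0.0798 to 0.0753 for stress response genes. The unadjusted p of the list test went from 0.0040 to 0.0067 and from 0.0024 to 0.0027. Both adjusted values had been close to the threshold. Each difference kept its size with the covariate and without the array of narrow signal range. Both calls held without that array, which argues against this 1 array as the whole cause of either. Neither call held with the covariate, so signal range differing between arrays is left open. The histone list also fell in unirradiated knockout cells from 4 h to 24 h (-0.24, against 0.04 in parental cells), by 0.11 without knockout 0 Gy, 24 h replicate 3. The stress response list moved by 0.10 (0.01 in parental cells). Neither change in knockout cells passed the list test with an estimated correlation (adjusted p = 0.22 and 0.58). For histone genes, 0.5 of the parental response lies within 1 SE (0.13, of the list means) of the -0.24. Time in culture may therefore account for part of that difference. For stress response genes the answer depends on the measure, since 0.10 is a median and the SE (0.06) is of list means. In list means, unirradiated knockout cells went from 6.94 at 4 h to 7.03 at 24 h. Parental cells at 24 h went from 7.06 at 0 Gy to 7.36 at 2 Gy. Time in culture is left open for the stress response genes. An effect of SLFN11 on the stress response genes is a hypothesis that this single derivative cannot separate from other differences of the line.

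The splits of the 6 arrays of a pair of groups number 10, the real one included, too few for a share under 0.05. The real split called 2081, 2046, 2123 and 2117 genes between the lines, against at most 1, 0, 0 and 0 in the others (1 of 10 splits as large each). For irradiation in parental cells it called 40 and 12, against at most 1 and 0. In knockout cells and over time it called 0, with 1, 0, 0 and 1 as the highest others, and for the difference of the responses 0, with 2 at 4 h and 12 at 24 h. Where the real count is 0, every split is as large by definition (10 of 10, and 100 of 100 draws), so these counts decide nothing about chance. For the lines over the 4 conditions together, the real labels called 5385 genes and 99 other draws at most 1 (1 of 100 as large). This argues against a chance assignment of these arrays to the 2 lines. With 100 draws no smaller share was possible, and arrays were permuted as independent although replicates may be technical.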

How the results depend on the processing

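SLFN11 kept its direction and call between the lines in every setting (-1.27 to -1.60 with 1 array left out), and each line comparison kept within 1.5 times its count. With 1 array left out these counts ran from 1562 to 1797 and 1558 to 1790 at 0 Gy and from 1665 to 2188 and 1586 to 1862 at 2 Gy (4 h and 24 h). With the replicate block, irradiation called 61 (parental, 4 h; 1 higher), 60 (parental, 24 h; 45 higher and 15 lower) and 11 (knockout, 4 h) genes, time 1 (parental) and 18 (knockout), and the difference of the responses at 24 h 3. The block with only the compared arrays (added after the data were seen) called 78, 86, 18 and 42 for irradiation (parental 4 h and 24 h, knockout 4 h and 24 h) and 68 for time in knockout cells. In the other 3 paired comparisons, the block over all arrays called 2598 genes between the lines at 0 Gy, 4 h (against 2081), 2683 at 2 Gy, 24 h (against 2117) and 0 for irradiation in knockout cells at 24 h. It changed no list call in the 4 paired comparisons.

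In parental cells at 4 h, 40 became 24 without the intensity trend and 67 with array weights (22 to 44 with 1 array left out); at 24 h, 12 became 7 and 22, 28 with only the compared arrays, 4 without both narrow-range arrays (added later), and 3 to 7 with 1 array left out. In knockout cells at 4 h, 0 became 1 without the trend, 5 with array weights, 2 without both narrow-range arrays and 0 to 1 with 1 array left out; at 24 h it became 1 with only the compared arrays. The cause was not tested. With an estimated correlation 7 list calls were left, against 57.

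SLFN11 after irradiation, never called, changed sign in parental cells at 24 h (-0.0057 with equal medians; -0.093 to 0.070 without 1 array) and in the 4 h difference of responses (-0.26 to 0.058 without 1 array). Without 1 array, CHAC1 (-0.049 to 0.32) and JUN (-0.35 to 0.15) in knockout cells at 24 h, both uncalled, also did, as did the median of mitosis genes over time in knockout cells (-0.13 to 0.014). Of the other values of named genes, 5173 kept their side of the threshold, 160 lost it and 13 gained it; of list values 853 kept and 224 lost it. Without dim genes, 263 values of named genes were left and none lost its call; a gene not above background in 1 group has only a bound on its fold.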

Other observations

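Genes that neighbour each other shifted together between the lines. Over a running window of 101 neighbouring genes, the median line difference reached 0.41 in size, and 12 stretches passed the level of 0.08 that random gene orders reached in 5% of 1000 draws. The shortest were SLC7A9 alone, PHKB to ADCY7 (13 genes) and MAEA to RNF4 (15 genes), too short to read as regional shifts by themselves. Windows were not stopped at chromosome ends, so those near an end mix chromosomes. From CSNK2A1 to ZNF133, 89 of 106 genes were lower in knockout cells, with a median of -0.72 over the 38 with a mean signal above 6. From CNTN4 to ARPP21, 103 of 129 were higher, with a median of 0.49 over the 61 above 6. Another long stretch ran from WASHC2A to KNDC1 (343 of 462 higher), which holds FAS, ACTA2, HHEX and the mitosis genes MKI67, CDK1 and KIF11. Further ones ran from TAAR2 to WDR27 (116 of 152 higher) and from ROR1 to BOLA1 (245 of 334 lower), which holds SYCP1. The 9 stretches found on the 4 h arrays alone hold 8.80% of all ordered genes and 24.9% of the genes called the same way in both line comparisons on the 24 h arrays.

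The test of random gene order and the share of called genes were chosen after the stretches were seen. Random order is excluded: the observed order was the 1 of 1001 with as large a running median, against at most 0.10 in the others. Stretches found on the 4 h arrays alone were then read on the 24 h arrays. Genes with a mean above 6 shifted by 0.32 (median, 599 of 674 in the direction of their stretch) and genes near background by 0.018 (261 of 485), which argues against a background or array surface effect. A candidate explanation is a copy number difference between the parental line and the derivative; regional regulation would look the same in RNA, and no DNA was analysed here.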
